A study of Mus musculus with 6 samples.

How the data were processed

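RNA was measured by sequencing in cultured mouse neurons. Per the labels, hippocampal neurons were taken from C57bl/6 embryos at day 16.5, kept 10 days in culture and then left untreated or exposed to 55 mM KCl for 0.5 h or 3 h. Raised KCl depolarises neurons and is a standard way to mimic activity. Each of the 3 groups has 2 libraries, 6 in all, made per the labels with TriReagent RNA and the TruSeq RNA library kit v2, which does not mark the strand. The submitters' processing notes name the mouse genome build mm9 and Bowtie; software versions, the gene annotation and the handling of reads that match several places are not given in the sources used here.

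Each deposited library lists 22667 genes by Ensembl identifier with a pair of values and no column names. The first value is an RPKM computed by the authors and named cRPKM as deposited, without a definition in the sources used here. It was taken to be reads per kilobase of effective gene length, normalized to the library total; that the c stands for a correction of gene length was assumed. The other deposited value is a whole-number read count per gene, which the authors left without normalization. The cRPKM was checked against the counts: over 7262 genes with more than 2000 counts in each library, the ratio of count to cRPKM followed a single factor per library, equal to the ratio of library totals, within 0.167%. No value is given for 1114 genes in any library, and 2065 of the 21553 genes with values were at 0 in all of them. The total count per library ran from 98882007 to 141865913, and the gene with most counts, mt-Co1, took 1.13% to 1.49% of them. At this depth counting error is small beside the difference between replicates: the chi-square between the 2 libraries of a group averaged 116, 121 and 239 per gene in the untreated, 0.5 h and 3 h groups, where reads drawn from 1 library would give 1.

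Identifiers were matched to gene symbols in a GENCODE mouse annotation of a later build, which named 20451 of the 21553 genes (94.9%). That annotation was used for names, neighbouring genes, transcript length and GC content; the deposited values carry no positions, and none are given. The deposited tables hold 1 value pair per gene, so exon inclusion was not analysed here.

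Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with a minimum count of 10 (15895 genes kept, holding 99.99% of all counts), and the quasi-likelihood F test on 1 fit of all 6 libraries with group as the only term, which leaves 3 residual degrees of freedom (prior degrees of freedom 2.75, common biological coefficient of variation 19.2%). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called higher or lower. The comparisons were 0.5 h against untreated, 3 h against untreated and 3 h against 0.5 h, the last being also the test of the difference between the KCl effects at both times. Fold changes are log2 values with the standard error of the fit; levels are mean cRPKM with the SD of 2 libraries.

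Both replicates of a group are numbered, without a stated culture or day. The differences between replicates 1 and 2, taken per gene, correlated across 15895 genes with r = 0.81 between untreated and 0.5 h, 0.58 between untreated and 3 h, and 0.61 between 0.5 h and 3 h; genes are not independent replicates. The first principal component (52.8% of variance) followed time and the other leading component (33.2%) separated the numbers in all 3 groups. The numbers were therefore read as a pairing, which comes from the data and not from the labels, and each fit was repeated with replicate number as a block; the blocked value stands beside a result where it changes the call or moves a count by more than 1.5 times.

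The groups, the tests, the rule for named genes, 33 gene lists and most alternatives were set before the data were examined. The rule took the 10 largest rises and 10 largest falls against untreated (5 each way between the times) among genes past the threshold with a symbol, a mean cRPKM of at least 1, and both libraries of one group on the same side of both libraries of the other. It also took Srrm4 and each neural splicing regulator past the threshold in any comparison, and for each list up to 4 members with the smallest adjusted p. The lists hold 888 genes, 881 of them measured: immediate early genes, activity effectors, signalling inhibitors, neural splicing regulators, general splicing factors, genes with neural microexons, autism genes, excitatory synapse, inhibitory synapse, presynaptic genes, potassium channels, calcium and sodium channels, large adhesion genes, heat shock, unfolded protein response, p53 and apoptosis, sterol synthesis, glycolysis, respiratory chain, ribosomal proteins, clock genes, chromatin and transcription coregulators, cytokines and immune genes, and 10 lists of cell type markers (pan-neuronal, excitatory neuron, interneuron, astrocyte, oligodendrocyte lineage, microglia, endothelial, fibroblast, progenitor and erythroid). Lists with at least 5 tested genes were tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, which asks whether the genes of a list move one way without comparing them with other genes. Both were adjusted by Benjamini-Hochberg over the lists of a comparison. For each list, members were also counted after adjustment over the list alone.

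The alternatives were DESeq2 1.42.0 size factors, DESeq2 itself, library totals alone, no filter, a cRPKM of at least 5 in 2 libraries, limma on log2 cRPKM with 0.1, 1 or 5 added, the replicate block, only the 4 libraries compared, a 2-fold minimum, an adjusted p under 0.01, and each library left out in turn. A correction for transcript length and GC content, that correction with the block, DESeq2 with the block and a mean cRPKM of at least 1 were added after the data had been seen; the length and GC trend took 0.466% to 3.51% of the variance per library over 15605 genes. With 1 library of a group left out, the lone library is assumed to vary like the others. Groups of 2 give too few regroupings of the samples for a permutation p under 0.05, so none is given.

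The procedure was tested on simulated data with the dispersion of these libraries and 200 changed genes. At 0.5 h it called 49.3% of genes changed 2-fold, 82.1% of those changed 4-fold and 97.0% of those changed 16-fold. These were 33, 55 and 64 true calls, beside 10 false calls among 15895 genes. At 3 h the shares were 59.7%, 85.1% and 97.0%, or 40, 57 and 64 true calls, beside 14 false ones. The simulated libraries did not carry the replicate pairing found in the data. A raised list was called at both times, and 0 of 30 unchanged lists were. The simulated genes were drawn independently of one another, so this does not show how often lists of correlated genes would be called falsely. In the data the estimated correlation at 3 h was 0.43 for the excitatory synapse list and 0.282 for the ribosomal proteins. Since both KCl times share the untreated libraries, the overlap of their responses was set beside 100 simulations of unchanged groups against the same controls. These drew the libraries independently; 100 further simulations, added after the result was seen, kept each gene's replicate effect and used the dispersion of the blocked fit.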

Results

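Gene expression was measured in cultured mouse hippocampal neurons that were untreated or had been in 55 mM KCl for 0.5 h or 3 h, with 2 libraries per group. The study's title names an activity-dependent splicing network and autism, and the comparisons ask which genes respond to depolarisation early and late. The untreated libraries held 141865913 and 133219004 counts, those at 0.5 h 136170697 and 115900044, and those at 3 h 140048704 and 98882007. The labels call the libraries of a group biological duplicates, without stating what was duplicated, so p-values measure the spread between these samples. Levels are given as mean cRPKM ± SD (n = 2) and changes as log2 fold change ± SE.

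After 0.5 h of KCl, a small set of rapid response genes rose steeply. The transcription factor gene Fos (ENSMUSG00000021250) went from 8.06 ± 0.11 cRPKM in untreated neurons to 230 ± 9.9 (SD, n = 2). This is 28.1-fold. Klf4 (ENSMUSG00000003032), another transcription factor gene, rose from 0.69 ± 0.13 to 10.8 ± 1.6. Nr4a1, which encodes a nuclear receptor, rose from 10.5 ± 1.2 to 110 ± 16. The matrix protein gene Ccn1 rose from 2.68 ± 0.092 to 36.9 ± 5.1 and the synaptic gene Arc from 4.13 ± 0.75 to 31.8 ± 6.7. The MAP kinase phosphatase gene Dusp1 rose from 6.68 ± 1.1 to 37.6 ± 1.7 (SD, n = 2 each). Their log2 changes were 4.81 ± 0.19 for Fos, 3.93 ± 0.25 for Klf4, 3.76 ± 0.24 for Ccn1, 3.37 ± 0.15 for Nr4a1, 2.92 ± 0.22 for Arc and 2.47 ± 0.14 for Dusp1. In edgeR's quasi-likelihood test the Benjamini-Hochberg adjusted p was 0.0063 for Fos and Nr4a1, 0.018 for Dusp1, 0.019 for Klf4 and Ccn1, and 0.043 for Arc. Each was higher in both treated libraries than in both untreated ones. These 6 were the only genes called higher among 15895 tested, and 0 were called lower. At an unadjusted p under 0.05, 100 genes were higher and 28 lower. That is well below the share of 0.05 that unchanged genes alone would give. The fit without the block takes the replicate differences that recur in every group into its spread and was strict at 0.5 h. The few calls therefore do not measure how many genes responded. DESeq2 called 35 and 2, limma 11 and 2, and the fit with the replicate block 13 and 0, among them all 6. Arc's adjusted p was 0.05 with the block. Without untreated replicate 1 or untreated replicate 2, none of the 6 kept its call (adjusted p 0.052 to 0.19 and 0.062 to 0.14). Without the first or the other 0.5 h library 2 and 3 kept it, and without either 3 h library 3 did.

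Several familiar immediate early genes had large values at 0.5 h without passing the test. Fosb stood at 1.12 ± 0.50 cRPKM in untreated neurons and 62.4 ± 1.7 at 0.5 h (SD, n = 2), a log2 difference of 5.79 ± 0.47 (adjusted p = 0.052, edgeR). Npas4, named here after its values were seen, stood at 4.70 ± 0.21 and 106 ± 7.5, a log2 difference of 4.48 ± 0.37 (adjusted p = 0.054; 0.03 with the replicate block). Gadd45g stood at 25.0 ± 2.3 and 76.7 ± 12 (adjusted p = 0.067; 0.013 with the block). Over the list of immediate early genes, 3 of 29 members passed (Fos, Nr4a1 and Klf4), 19 did when adjusted over the list alone, and 7 did with the block, with a median log2 change of 1.34. Without untreated replicate 1 or 2 the count was 0, and without either 0.5 h library it was 2. The list as a whole rose against other genes (camera adjusted p = 3.2e-248; adjusted p = 0.0042 with an estimated correlation).

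Of the activity effectors, which are secreted, synaptic and signalling proteins made after activity, 2 of 40 passed at 0.5 h (Ccn1 and Arc; 5 adjusted over the list alone), and of the signalling inhibitors 1 of 23 (Dusp1, and 3 adjusted over the list alone). Both lists were called higher by camera (adjusted p = 7.5e-26 and 3.4e-21), but not with an estimated correlation (adjusted p = 0.26 and 0.12). The inhibitors had 0 members called whichever library was left out. The effectors had 0 without untreated replicate 1, untreated replicate 2 or 0.5 h replicate 1, and 1 without 0.5 h replicate 2 or either 3 h library. The other 30 lists had 0 members called by edgeR, 0 adjusted over each list alone and 0 with the block. At an unadjusted p under 0.05 they had 3 higher and 1 lower. DESeq2 called 0 and 1, and limma called 0. The 1 lower gene was a progenitor marker in both cases. Small shifts of whole lists were called by camera all the same: general splicing factors (median 0.05, adjusted p = 0.012) and p53 and apoptosis genes (median 0.05, adjusted p = 0.009) higher. It called excitatory synapse (median −0.10, adjusted p = 1.6e-05), inhibitory synapse (−0.09, 0.0026), presynaptic (−0.09, 0.00065), potassium channel (−0.09, 0.00032), calcium and sodium channel (−0.07, 0.0028), large adhesion (−0.09, 0.00041) and autism genes (−0.05, 0.0028) lower. None of these held with an estimated correlation (adjusted p = 0.83 for general splicing and the synapse, channel and adhesion lists with an estimated correlation, 0.39 for p53 and 0.88 for autism genes). With the block, camera also called clock genes higher (adjusted p = 0.011) and sterol synthesis (0.0056), pan-neuronal (0.023) and oligodendrocyte (0.0019) genes lower. None of the 4 was called without the block when the correlation was estimated (adjusted p = 0.83, 0.96, 0.88 and 0.83 with an estimated correlation). Of these 30 lists, fry with the block called clock genes (adjusted p = 0.034) and microglia markers (0.02), both at 0.98 without it. Hes5, a target of Notch signalling in progenitors, stood at 14.2 ± 2.5 cRPKM in untreated neurons and 2.74 ± 0.34 at 0.5 h (SD, n = 2), with an adjusted p of 1.

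**Figure D1:**
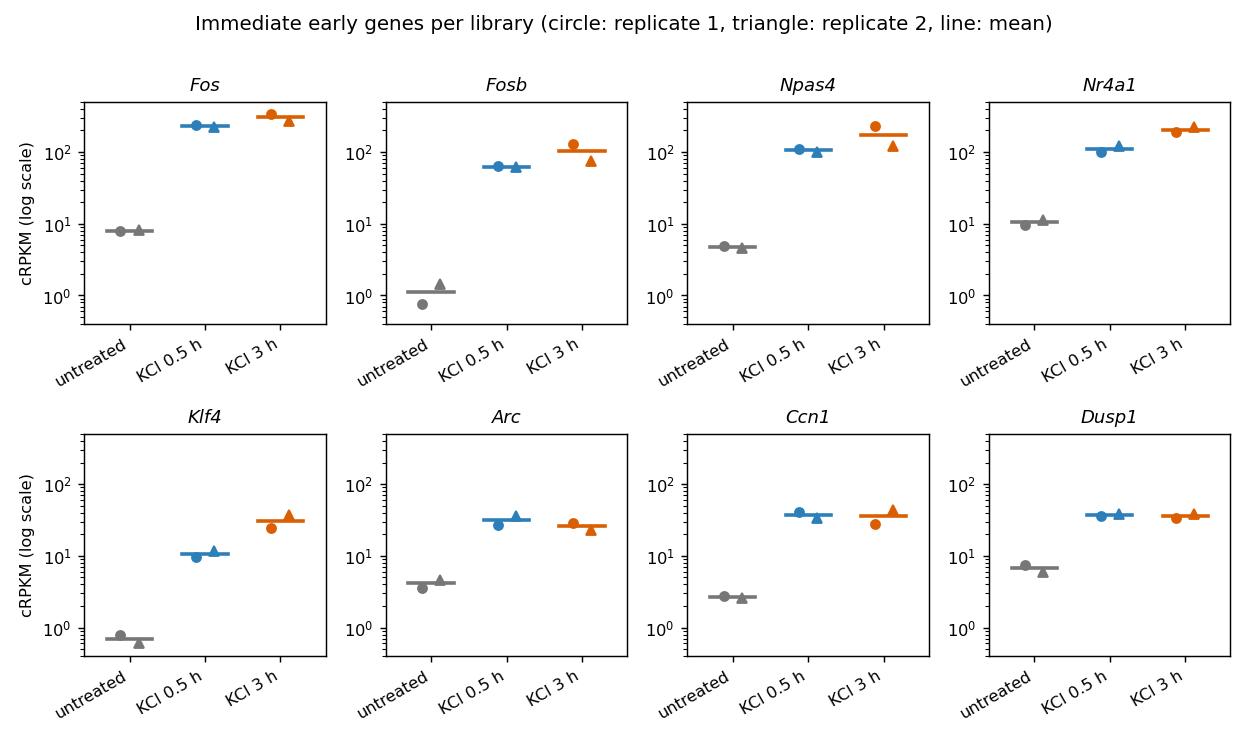
Expression of 8 activity-response genes in each library: cRPKM on a log axis against treatment, with a circle for replicate 1, a triangle for replicate 2 and a line for the mean of the 2 libraries. Fos goes from a mean of 8.06 in untreated neurons to 230 at 0.5 h and 308 at 3 h, while Arc and Dusp1 stand at similar levels at both KCl times.

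At 3 h, 2472 genes were called, far more than at 0.5 h. Transcription factor genes were again among the largest rises, taken over genes with a mean of at least 1 cRPKM: Fosb reached 102 ± 39 cRPKM, Fos 308 ± 52, Npas4 176 ± 79, Klf4 30.5 ± 8.9 and Nr4a1 206 ± 23 (SD, n = 2), 96.6-fold, 39.8-fold, 39.3-fold, 45.5-fold and 20.4-fold above untreated neurons. Fosl1, a further member of the Fos family, rose from 0.17 ± 0.014 to 6.38 ± 2.5. Maff, a small Maf factor, rose from 1.24 in both libraries to 22.4 ± 3.4, and Ptgs2, the inducible cyclooxygenase, from 0.15 ± 0.085 to 3.68 ± 0.76. The smooth muscle calponin gene Cnn1 rose from 0.12 ± 0.028 to 7.18 ± 7.6, with 1.82 and 12.5 cRPKM in the 2 libraries. The transcript 4931440P22Rik rose from 0.415 ± 0.021 to 10.7 ± 5.8. The log2 changes of these 10 ran from 4.24 ± 0.21 (Maff) to 6.59 ± 0.48 (Fosb), with edgeR adjusted p from 0.0014 to 0.020. Fosb, Klf4, Fos, Ptgs2, Nr4a1 and Maff kept their calls whichever library was left out. Cnn1, Fosl1 and 4931440P22Rik lost theirs without untreated replicate 1 (adjusted p = 0.11, 0.063 and 0.059) and without untreated replicate 2 (0.12, 0.068 and 0.068), and Npas4 without the latter (0.057).

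The largest fall at 3 h was that of Txnip, whose product binds thioredoxin and restrains glucose uptake, from 39.3 ± 11 to 3.98 ± 2.6 cRPKM (SD, n = 2), a log2 change of −3.27 ± 0.50. Among the other 9 of the 10 named falls were zinc finger genes (Zkscan16, −2.09 ± 0.25; Zfp759, −1.87 ± 0.27; Zkscan4, −1.84 ± 0.22; Zc3h6, −1.90 ± 0.23) and Hif3a, a hypoxia-inducible factor subunit (−2.00 ± 0.23). The remaining falls were of Dact2, a modulator of Wnt signalling (−1.97 ± 0.16), Gprin2 (−1.83 ± 0.30), the receptor gene Tnfrsf18 (−1.82 ± 0.39) and the transporter gene Slc16a9 (−1.81 ± 0.39). The adjusted p ran from 0.0059 to 0.036 in edgeR. Each of the 20 named genes had both 3 h libraries on the same side of both untreated ones. Without untreated replicate 1, 3 of the 10 falls kept their call (adjusted p 0.044 to 0.1 over the 10), and without untreated replicate 2 none did (0.06 to 0.19). Slc16a9 also lost it without either 0.5 h library (0.063 and 0.061), Tnfrsf18 without either 3 h library (0.084 and 0.11) and Gprin2 without 3 h replicate 2 (0.059).

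At 3 h, 1384 genes were called higher and 1088 lower of 15895 tested. Of these 583 and 256 changed at least 2-fold. With the replicate block the counts were 2963 and 2955, holding all of the former, and DESeq2 gave 2276 and 1857. Scaling by library totals gave 1115 higher and 1340 lower, and limma 963 and 1312, so the larger side depends on the scaling. The counts were far lower without either untreated library, in fits with fewer degrees of freedom and a lone untreated library. This does not show whether the changes depend on both. The counts were also lower without either 0.5 h library or without 3 h replicate 2, and higher without 3 h replicate 1.

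The activity lists rose broadly at 3 h. Of the immediate early genes, 25 of 29 rose and 1 fell (26 and 1 adjusted over the list alone), with a median log2 change of 2.46. The exception was Klf10 (−1.10 ± 0.13), named after its values were seen. Of the activity effectors, 30 of 40 rose and none fell (31 adjusted over the list alone; 32 higher and 2 lower with the block), with a median of 1.67. The stress-inducible Gadd45g rose from 25.0 ± 2.3 to 198 ± 28 cRPKM (SD, n = 2; log2 change 3.04 ± 0.15). The synaptic pentraxin gene Nptx2 rose by 1.41 ± 0.09, Fbxo33 by 2.30 ± 0.13 and Tiparp by 1.92 ± 0.12. Bdnf, which encodes a neurotrophin and was named after its values were seen, stood at 9.36 ± 3.3 in untreated neurons, 9.61 ± 3.0 at 0.5 h and 49.0 ± 9.2 at 3 h (log2 change at 3 h 2.45 ± 0.34, adjusted p = 0.013). Of the inhibitors of MAP kinase, CREB and growth factor signalling, 16 of 23 rose and 2 fell (18 and 2 adjusted over the list alone), with a median of 1.08. The phosphatase genes Dusp1 (2.47 ± 0.14), Dusp16 (2.06 ± 0.17) and Dusp10 (1.60 ± 0.14) and the eIF2 phosphatase subunit gene Ppp1r15a (1.70 ± 0.11) were among the risers. Those that fell, named after their values were seen, were Socs2 (−0.87 ± 0.19) and Dusp2 (−0.91 ± 0.22). Camera called the 3 lists higher (adjusted p = 2.4e-35, 6.7e-27 and 2.8e-12), but not with an estimated correlation (adjusted p = 0.091, 0.21 and 0.21). Fry called all 3 as moving up (adjusted p = 0.0049, 0.017 and 0.017). Without untreated replicate 1, 11 immediate early genes, 9 effectors and 4 inhibitors were called higher, and without untreated replicate 2 the counts were 8, 9 and 1. Klf10 was not called lower without either untreated library. Of the 2 inhibitors that fell, 1 was called without 3 h replicate 1, and 0 with any other library left out. Gadd45g, Nptx2, Fbxo33, Tiparp and Dusp1 kept their calls with any library left out. Dusp10 lost its call without untreated replicate 1 (adjusted p = 0.061), and Dusp16, Dusp10 and Ppp1r15a lost theirs without untreated replicate 2 (0.064, 0.066 and 0.052).

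Srrm4 (ENSMUSG00000063919), which encodes a neural activator of microexon splicing, did not pass the test at either time. It stood at 12.7 ± 0.47 cRPKM in untreated neurons, 12.3 ± 0.56 at 0.5 h and 17.3 ± 6.0 at 3 h (SD, n = 2), with 21.6 and 13.1 cRPKM in the 3 h libraries. Its log2 change was −0.07 ± 0.25 at 0.5 h (adjusted p = 1) and 0.52 ± 0.25 at 3 h (adjusted p = 0.21, edgeR; 0.1 with the block). The change at 3 h was 0.88 without 3 h replicate 2 (adjusted p = 0.021), without 3 h replicate 1 it was 0.06 (0.68), and DESeq2 with the block gave 0.49 (0.018).

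Other splicing regulators did change at 3 h. Ptbp1, a repressor of neural exons, rose from 15.4 ± 1.9 to 76.3 ± 31 cRPKM (SD, n = 2; log2 change 2.35 ± 0.26, adjusted p = 0.0087), with 54.7 and 98.0 cRPKM in the 2 libraries. The muscleblind genes Mbnl2 (25.2 ± 6.9 to 74.8 ± 5.4; 1.63 ± 0.25, adjusted p = 0.016) and Mbnl1 (8.20 ± 0.35 to 14.1 ± 3.6; 0.83 ± 0.15, 0.024) rose. So did the RNA-binding protein gene Elavl1 (13.2 ± 0.59 to 17.7 ± 2.2; 0.48 ± 0.11, 0.044), while its neuronal relative Elavl2 fell (20.8 ± 0.77 to 14.2 ± 1.4; −0.49 ± 0.12, 0.043). These 5 were the members called among 30 neural splicing regulators, 4 higher and 1 lower, and the same counts held adjusted over the list alone. With the block 8 were higher and 3 lower. The list had a median of −0.04 and a mean of 0.10, and camera did not call it (direction up, adjusted p = 0.86). None of the 5 kept its call without untreated replicate 1 (adjusted p 0.061 to 0.15) or untreated replicate 2 (0.068 to 0.26). Without either 0.5 h library, or without 3 h replicate 2, Elavl1 and Elavl2 lost theirs (adjusted p 0.068 to 0.099), and Elavl1 had an adjusted p of 0.065 with library totals. Without 3 h replicate 1, 4 members of the list were higher and 10 lower.

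Of the general splicing factors, 14 of 54 rose and 1 fell at 3 h (25 and 2 adjusted over the list alone; 28 and 2 with the block), with a median log2 change of 0.33. Tra2a, a regulator related to SR proteins, rose from 36.5 ± 1.5 to 90.6 ± 24 cRPKM (SD, n = 2; 1.36 ± 0.16, adjusted p = 0.0099). U2af1, which binds the 3′ splice site, rose by 0.66 ± 0.08 and the branch point factor gene Sf1 by 0.71 ± 0.10, while Tia1 fell by 0.71 ± 0.09 on the log2 scale. Camera called the list higher (adjusted p = 1.2e-06; adjusted p = 0.6 with an estimated correlation) and fry called it as moving up (0.031). No member was called without untreated replicate 1 or 2. Without either 0.5 h library 6 were higher, and without 3 h replicate 2, 8; without 3 h replicate 1, 2 were lower. Among 32 genes known to hold neural microexons 0 were called by edgeR, and 0 adjusted over the list alone, with a median of −0.10 (camera adjusted p = 0.5). At an unadjusted p under 0.05, 3 were higher and 3 lower. DESeq2 called 2 and 1, limma 0 and 2, and the block 2 and 2. EdgeR called 0 and 8 without 3 h replicate 1 and 2 and 0 without 3 h replicate 2. Mef2a (−0.41 ± 0.12) and Ptprd (−0.40 ± 0.13) had adjusted p of 0.081 and 0.096, and Cpeb2 (0.38 ± 0.12) and Macf1 (0.39 ± 0.14) of 0.092 and 0.11.

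**Figure D2:**
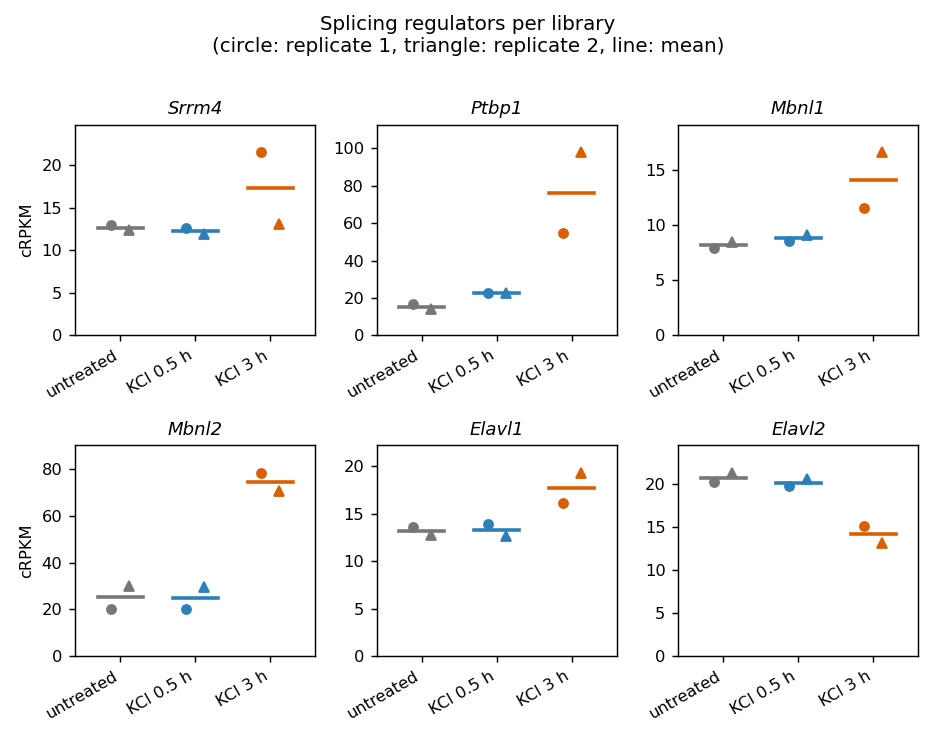
Expression of 6 splicing regulators in each library: cRPKM on an axis from 0 against treatment, with a circle for replicate 1, a triangle for replicate 2 and a line for the mean of the 2 libraries. Ptbp1 and Mbnl2 stand highest at 3 h in both replicates, whereas the 3 h libraries of Srrm4 lie apart, at 21.6 and 13.1.

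Genes of synapses and ion channels tended to lower values at 3 h. Of the glutamate receptor and postsynaptic scaffold genes, 10 of 48 fell and 2 rose (12 and 3 adjusted over the list alone; 18 and 4 with the block), with a median log2 change of −0.44. The adhesion gene Nlgn3 went from 26.6 ± 0.83 to 14.5 ± 0.78 cRPKM (SD, n = 2; −0.82 ± 0.11, adjusted p = 0.011). The glutamate receptor genes Grin3a and Grm7 changed by −0.59 ± 0.09 and −0.74 ± 0.12, and the auxiliary subunit gene Neto1 by −0.68 ± 0.12. Lrrtm2 (0.59 ± 0.11) and Dlg1 (0.71 ± 0.14), named after their values were seen, rose. Of the potassium channel genes, 10 of 52 fell and 1 rose (15 and 2 adjusted over the list alone; 25 and 2 with the block; median −0.42). Kcns2 fell from 2.67 ± 0.40 to 1.00 in both libraries (−1.36 ± 0.16), Kcnk3 from 3.84 ± 0.15 to 1.51 ± 0.27 (−1.29 ± 0.19), and Kcnv1 and Kcna2 changed by −1.13 ± 0.10 and −0.87 ± 0.11. The riser, named after its values were seen, was Kcnj2 (1.10 ± 0.26). Of the calcium and sodium channel and pump genes, 6 of 38 fell and none rose (6 adjusted over the list alone; 13 with the block; median −0.39). Among them were the calcium pump gene Atp2b2 (−1.07 ± 0.16), Cacna2d2 (−0.65 ± 0.09) and the sodium channel genes Scn3a (−0.80 ± 0.14) and Scn2a (−0.72 ± 0.13). The camera adjusted p of these 3 lists was 1.9e-06, 7.9e-07 and 2.3e-05, and each had adjusted p = 0.76 with an estimated correlation. No member was called without untreated replicate 1 or 2. The counts lower of the 3 lists were 4, 4 and 3 without either 0.5 h library, 23, 22 and 19 without 3 h replicate 1, and 3, 5 and 3 without 3 h replicate 2. No potassium channel gene was called higher with any library left out. Of the excitatory synapse genes 1 was higher without either 0.5 h library and 3 without 3 h replicate 1, where 1 calcium or sodium channel gene was higher too.

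The inhibitory synapse list had 3 of 24 members lower (2 adjusted over the list alone; 8 lower and 3 higher with the block; median −0.30), among them the GABA receptor genes Gabrg3 (−0.71 ± 0.12) and Gabrb2 (−0.82 ± 0.16). Of the large adhesion genes, 3 of 36 fell (3 adjusted over the list alone; 13 lower and 2 higher with the block; median −0.34): Il1rapl1 (−0.83 ± 0.13), Nrxn3 (−0.91 ± 0.17) and Erbb4 (−0.95 ± 0.19). Of the presynaptic genes only Syt4, a synaptotagmin, was called, from 111 ± 9.0 to 199 ± 51 cRPKM (SD, n = 2; 0.91 ± 0.22, adjusted p = 0.047), against a median of −0.37 over 32 genes (0 called adjusted over the list alone; 1 higher and 9 lower with the block). Camera called all 3 lists lower (adjusted p = 0.014, 0.0039 and 0.0015; adjusted p = 0.76 with an estimated correlation). Of the autism genes, 6 of 69 rose and 5 fell (the same adjusted over the list alone; 10 and 16 with the block; median −0.14, camera adjusted p = 0.16). The chromatin remodeller gene Chd2 rose from 11.6 ± 0.092 to 29.8 ± 2.9 (1.42 ± 0.12, adjusted p = 0.0061) and Ankrd11 by 0.61 ± 0.11. Zmynd8 fell from 17.7 ± 0.73 to 8.80 ± 0.33 (−0.95 ± 0.08, 0.0059). So did Nlgn3, Scn2a and, named after their values were seen, Tnrc6b (−0.64 ± 0.13) and Rai1 (−0.63 ± 0.14). None of these 4 lists had a call without untreated replicate 1 or 2. Fewer autism genes were called without either 0.5 h library. Syt4 lost its call there and also without 3 h replicate 1. Without 3 h replicate 1 there were 9 inhibitory synapse, 13 adhesion, 11 presynaptic and 18 autism genes lower. These were 1, 1, 0 and 4 without 3 h replicate 2, with 3 autism genes higher.

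Stress and clock genes rose in part at 3 h. Of the heat shock genes, 4 of 21 rose (4 adjusted over the list alone; 10 with the block; median 0.29): Dnajb4 (1.54 ± 0.13), Hspb8 (1.05 ± 0.17), Hspe1 (0.41 ± 0.08) and the co-chaperone gene Bag3 (3.89 ± 0.75), whose 3 h libraries stood at 10.6 and 50.1 cRPKM. Of the unfolded protein response genes, 5 of 25 rose (8 adjusted over the list alone; 11 with the block; median 0.25). Atf4 went from 185 ± 12 to 348 ± 22 cRPKM (SD, n = 2; 0.97 ± 0.15), and Dnajb9 rose by 1.49 ± 0.16, Sesn2 by 0.89 ± 0.10, Dnajc3 by 0.79 ± 0.12 and Hspa5, named after its values were seen, by 0.71 ± 0.14. Of the p53 and apoptosis genes, 6 of 25 rose and 2 fell (8 and 4 adjusted over the list alone; 10 and 5 with the block; median 0.19, camera adjusted p = 0.11). The survival gene Mcl1 (1.49 ± 0.13), Btg1 (1.06 ± 0.14) and the cell cycle inhibitor gene Cdkn1a (0.73 ± 0.11) rose. The death-promoting Bbc3 fell (−0.87 ± 0.12), as did Casp9 (−0.74 ± 0.12), named after its values were seen. Of the clock genes, 8 of 19 rose and 1 fell (10 and 3 adjusted over the list alone; 9 and 4 with the block; median 0.48). Nfil3 rose from 12.9 ± 2.2 to 86.2 ± 21 cRPKM (2.80 ± 0.29), as did Rorb (2.54 ± 0.25), Per1 (1.81 ± 0.20) and Cry1 (1.09 ± 0.12). Nfil3 and Per1 are also counted among the activity effectors, so the rises of these lists are not separate. Npas2, named after its values were seen, fell (−0.70 ± 0.10). Camera called the heat shock, unfolded protein and clock lists higher (adjusted p = 0.00064, 0.005 and 0.0022; adjusted p = 0.21, 0.6 and 0.6 with an estimated correlation). Fry called heat shock and clock genes as moving up (0.0096 and 0.039). With the block it also called p53 and apoptosis genes (adjusted p = 0.035, against 0.057 without it). Without untreated replicate 1 the survival gene Mcl1, of the p53 and apoptosis list, was the only member of these 4 lists to keep its call. Without untreated replicate 2 no member did. Without 3 h replicate 1, 9 unfolded protein genes were higher, and 2 clock genes and 1 heat shock gene lower. Without 0.5 h replicate 1 no clock gene was lower.

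Among metabolic lists, 4 of 24 glycolysis genes rose (4 and 1 lower adjusted over the list alone; 7 and 4 with the block; median 0.15, camera adjusted p = 0.22): the glucose transporter genes Slc2a1 (1.24 ± 0.20) and Slc2a3 (1.27 ± 0.23), the lactate transporter gene Slc16a1 (1.30 ± 0.16) and Pfkfb3 (0.55 ± 0.13). Of the ribosomal protein genes, 3 of 55 rose (0 adjusted over the list alone; 25 with the block; median 0.41), among them Rpl23 from 206 ± 2.7 to 269 ± 32 cRPKM (SD, n = 2) and Rps25 from 316 ± 2.7 to 424 ± 74. At an unadjusted p under 0.05, 39 were higher, and DESeq2 called 39 and limma 1. Camera called the list higher (adjusted p = 3e-08; adjusted p = 0.6 with an estimated correlation). Of the respiratory chain genes 0 of 50 were called by edgeR (0 adjusted over the list alone; 6 higher with the block; 8 higher at an unadjusted p under 0.05; 5 by DESeq2, 0 by limma; 5 without 3 h replicate 1), with a median of 0.14 (camera adjusted p = 0.024; adjusted p = 0.83 with an estimated correlation). Of the sterol synthesis genes only Msmo1 rose (0.58 ± 0.14, adjusted p = 0.045), 1 of 24 (0 adjusted over the list alone; 5 higher and 2 lower with the block), with a median of −0.03 but a mean of 0.07 (camera direction up, adjusted p = 0.75). Of the chromatin and transcription coregulators, 3 of 37 rose and 2 fell (the same adjusted over the list alone; 8 and 4 with the block; median 0.10, camera adjusted p = 0.26). The CREB coactivator gene Crebbp (0.66 ± 0.12), Ankrd11 and, named after its values were seen, Hdac4 (0.64 ± 0.12) rose. Tet1 (−0.71 ± 0.10) and Crtc1 (−0.62 ± 0.10) fell. Of the cytokine and immune genes, Nfkb1 (0.77 ± 0.10), Nfkb2 (1.60 ± 0.24) and Stat3 (1.12 ± 0.18) rose, 3 of 19 (3 adjusted over the list alone; 6 higher and 1 lower with the block; median 0.31, camera adjusted p = 0.11, 0.048 with the block). It had adjusted p = 0.76 with an estimated correlation and no block. Fry with the block called the glycolysis list (adjusted p = 0.035, against 0.47 without it). Its member Slc2a3 is also counted among the activity effectors. No member of these lists was called without untreated replicate 1 or 2. Without either 0.5 h library no ribosomal or sterol gene was called, and 1 coregulator was higher and 1 lower. Without 3 h replicate 1, 31 ribosomal genes were higher, no sterol gene was called and 1 glycolysis gene was lower. With 3 h replicate 2 left out, 1 ribosomal gene and 5 coregulators were higher and no sterol gene was called.

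**Figure D3:**
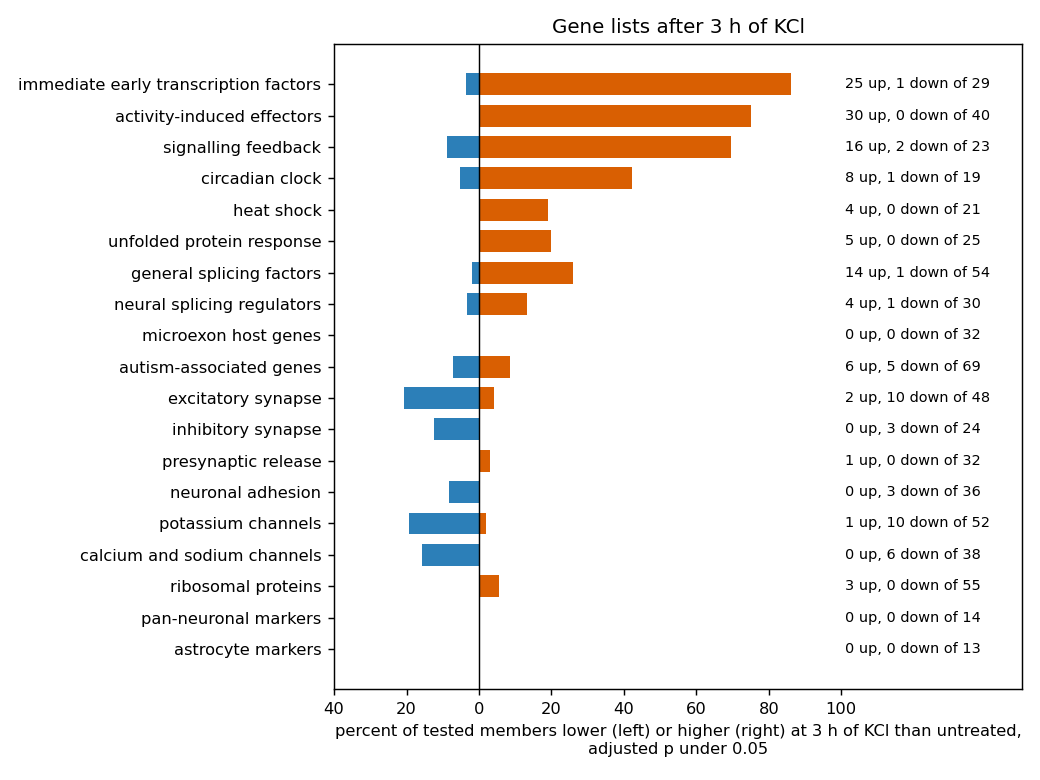
Share of the tested members of 19 gene lists called higher (right) or lower (left) at 3 h against untreated neurons, in percent, with the number called beside each bar. The immediate early genes (25 of 29) and activity effectors (30 of 40) stand out on the right, and the excitatory synapse (10 of 48) and potassium channel (10 of 52) lists lie mainly on the left.

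Few cell type markers were called at 3 h, although several lists had medians away from 0. Of the pan-neuronal markers 0 of 14 were called (median −0.20; 2 lower with the block), with the neuronal tubulin gene Tubb3 at 530 ± 110 cRPKM in untreated neurons and 206 ± 67 at 3 h (SD, n = 2; −1.30 ± 0.33, adjusted p = 0.051; 0.0031 with the block). Of the excitatory neuron markers only Neurod1 fell, from 9.98 ± 0.49 to 4.28 ± 1.3 (−1.15 ± 0.25, adjusted p = 0.037), 1 of 12 (median −0.22; 1 higher and 2 lower with the block). Of the progenitor markers Vim, an intermediate filament gene also found in astrocytes, rose by 2.09 ± 0.21 (adjusted p = 0.0073), 1 of 11 (median 0.57; 8 higher with the block; camera adjusted p = 0.031; adjusted p = 0.76 with an estimated correlation). No interneuron (15 genes, median −0.44; 1 higher and 6 lower with the block), astrocyte (13, 0.37; 4 and 1), oligodendrocyte (11, 0.28; 1 and 1), microglia (9, median 0.03 and mean −0.04), endothelial (10, 0.46; 1 and 1), fibroblast (10, 0.15; 2 and 0) or erythroid (4, −0.14) marker was called. The microglia median is −0.02 with library totals. Interneuron markers were called lower by camera with the block (adjusted p = 0.0025; 0.11 without it), as were pan-neuronal markers (0.048; 0.13 without it). Without the block these had adjusted p = 0.76 and 0.83 with an estimated correlation, and fry with the block gave 0.17 and 0.29. Among the cell type lists, fry with the block called progenitor (adjusted p = 0.036) and fibroblast markers (0.035), which had 0.24 and 0.94 without it. Over all 10 lists, 9 markers were higher and 9 lower at an unadjusted p under 0.05. DESeq2 called 5 and 8, and limma 2 and 3. Adjusted over each list alone, only Vim was called. No marker was called without untreated replicate 1 or 2. Without either 0.5 h library or 3 h replicate 2 Neurod1 lost its call (adjusted p = 0.059, 0.057 and 0.059). Without 3 h replicate 1, 3 pan-neuronal, 3 excitatory, 2 interneuron, 1 oligodendrocyte and 1 progenitor marker were lower and 4 astrocyte markers higher.

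The replicates themselves differed in several sets of cell type markers. The transthyretin gene Ttr, an abundant choroid plexus transcript, stood at 0.08, 0.04 and 0.13 cRPKM in replicate 1 and at 136, 189 and 229 in replicate 2 of the untreated, 0.5 h and 3 h groups. Fibroblast markers were higher in replicate 2 by a median log2 difference of 0.76, 0.77 and 1.01 in the 3 groups and interneuron markers by 0.53, 0.56 and 0.43. For astrocyte markers it was 0.24, 0.35 and 0.66, and for oligodendrocyte markers 0.32, 0.41 and 0.50. Some single genes, named after their values were seen, differed far more. Gfap stood at 22.4, 22.8 and 24.6 cRPKM in replicate 1 and at 307, 335 and 475 in replicate 2. The log2 difference in the blocked fit was 4.6 for Gpr17 and 4.65 for Col1a2. Of 13 astrocyte markers, 11 were higher and 0 lower in replicate 2 in all 3 groups. Sterol synthesis genes (−0.33, −0.42 and −0.66) and progenitor markers (−0.62, −0.48 and −0.34) had lower medians in replicate 2. Other sets differed unevenly between the groups: pan-neuronal (−0.15, −0.22 and −0.56), excitatory neuron (−0.03, −0.18 and −0.64) and endothelial markers (−0.05, 0.08 and −0.46). The synapse and channel lists, with negative medians at 3 h, differed little between replicates in untreated neurons (medians 0.11 to 0.21 higher in replicate 2) and were lower in replicate 2 at 3 h (−0.24 to −0.38).

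Between 0.5 h and 3 h the response gained members. Late genes, none of them called at 0.5 h, rose from then to 3 h: Fosl1 by 5.12 ± 0.51, Cnn1 by 6.30 ± 1.03, 4931440P22Rik by 4.11 ± 0.45, C2cd4b by 3.55 ± 0.25 and the stress transcription factor gene Atf3 by 3.43 ± 0.21 on the log2 scale (adjusted p 0.0077 to 0.024, edgeR). The largest falls were those of Txnip (−2.55 ± 0.49), the collagen gene Col15a1 (−2.12 ± 0.33), Hif3a (−2.06 ± 0.23), Zkscan16 (−2.05 ± 0.25) and Six5 (−1.94 ± 0.27), with adjusted p 0.012 to 0.034. Ptbp1 (1.83 ± 0.26, adjusted p = 0.017), Mbnl2 (1.67 ± 0.25, 0.020), Mbnl1 (0.74 ± 0.15, 0.038) and Elavl1 (0.49 ± 0.11, just under 0.05) were higher at 3 h than at 0.5 h. Elavl2 was at −0.43 ± 0.12 (0.069; 0.034 with the block), and Srrm4 at 0.59 ± 0.25 (0.18). In all, 1015 genes were higher and 774 lower, with 2477 and 2484 in the block, 1942 and 1606 in DESeq2, 762 and 1037 with library totals (which moves the median of all genes from −0.028 to −0.104) and 671 and 1039 in limma. Without 0.5 h replicate 1 or 0.5 h replicate 2, 0 genes were called, and none of the named genes kept its call (adjusted p 0.08 to 0.26). The counts were 367 and 136 without untreated replicate 1, 369 and 143 without untreated replicate 2, 1552 and 1399 without 3 h replicate 1, and 780 and 509 without 3 h replicate 2.

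By list, 24 of 40 activity effectors were higher at 3 h than at 0.5 h and 0 lower (29 and 0 adjusted over the list alone), as were 14 of 29 immediate early genes with 1 lower (15 and 2 adjusted over the list alone), 9 of 23 signalling inhibitors with 1 lower (14 and 2; 16 and 2 with the block), and 8 of 54 general splicing factors with 1 lower (18 and 2; 21 and 2 with the block). Nptx2 (1.48 ± 0.09), Gadd45g (1.44 ± 0.14), Nr4a3 (2.21 ± 0.14), Dusp16 (1.86 ± 0.17) and Tra2a (1.18 ± 0.16) were among those higher. Those lower were Klf10 (−0.91 ± 0.13), Socs2 (−0.86 ± 0.19) and Tia1 (−0.75 ± 0.09). Of the potassium channel genes 7 of 52 were lower (9 adjusted over the list alone; 19 with the block) and 1 higher (Kcnf1, 0.72 ± 0.17). Of the excitatory synapse genes 5 of 48 were lower (8 adjusted over the list alone; 14 with the block), namely Nlgn3, Grm7, Grin3a, Neto1 and Grik1, and Lrrtm2 and Dlg1 higher. Of the clock genes 8 of 19 were higher and 1, Npas2, lower (9 and 3 adjusted over the list alone; 9 and 4 with the block). Klf10, Socs2, Kcnf1, Neto1, Grik1, Dlg1 and Npas2 were named after their values were seen. Camera called 10 lists higher and 5 lower, and 0 of either with an estimated correlation (adjusted p = 0.24 for effectors, immediate early genes and inhibitors, 0.64 for general splicing, and 0.83 for the channel and synapse lists with an estimated correlation). With the block it also called inhibitory synapse (adjusted p = 0.016) and interneuron genes (0.0034) lower, both at adjusted p = 0.83 with an estimated correlation in the fit without the block. No member of any list was called without 0.5 h replicate 1 or 0.5 h replicate 2. Without either untreated library the counts higher were 20, 10, 6 and 1 for effectors, immediate early genes, inhibitors and general splicing factors, the counts lower were 2 and 0 for potassium channels and excitatory synapse, and the clock genes had 6 higher. Of those higher or lower in small number, 2 immediate early genes, 1 splicing factor and no inhibitor or clock gene were then lower, and no channel or excitatory synapse gene higher. The counts lower for excitatory synapse and potassium channels were 17 and 17 without 3 h replicate 1 and 2 and 4 without 3 h replicate 2, and those of potassium channels higher 0 and 2. General splicing factors had 2 lower without 3 h replicate 1, and the inhibitors 0 without 3 h replicate 2.

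All 6 genes called at 0.5 h were also called higher at 3 h, where independent lists of these sizes would share 0.52. Both comparisons use the same untreated libraries: 100 simulations of unchanged groups of independent libraries against those controls shared a mean of 0.12 and at most 2 genes. Across 13934 genes, which are not independent replicates, the fold changes at both times had a covariance of 0.0462 against 0.0437 in the simulations, a correlation of 0.47 against 0.50, and the same sign in 66.8% of genes against 66.6%. In 100 simulations that kept the replicate effect of each gene, the covariance was 0.0131 without the block and 0.0129 with it (at most 0.0142 and 0.0140), the correlation again 0.50, and at most 0 and 3 genes were shared, against 6 and 13 observed. The shared calls were more than any simulation gave. Unchanged groups yield few calls of any kind, with a mean of 1.1 in the simulations of independent libraries. Any response called at both times would exceed them, so the count does not show how much of the overlap comes from the shared controls. With the replicate effects found in these data kept, the covariance over all genes was also above the largest simulated value; the value of 0.0437 leaves the pairing out.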

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

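No test below was chosen only after its result was seen. The difference between the KCl effects at 3 h and 0.5 h was itself tested, as 3 h against 0.5 h in the same edgeR fit, and it passed for many genes: 1015 were higher and 774 lower at 3 h (2477 and 2484 with the replicate block). Among the genes called at 0.5 h, the effect grew for Klf4, by a log2 difference of 1.57 (adjusted p = 0.017), and for Nr4a1, by 0.98 (adjusted p = 0.017); both 3 h libraries of each were above both 0.5 h libraries. These calls were lost without either 0.5 h library, in fits with fewer degrees of freedom and a lone 0.5 h library. This does not show whether the differences depend on both. The genes behind the counts, and the values of the larger changes, stand in the account of the comparison between the times.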

How the results depend on the processing

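The tests after correction for length and GC content, the block with that correction, DESeq2 with the block, the filter on mean cRPKM and the simulation that keeps replicate effects were chosen only after the data were seen. Of 424 results for named genes, 166 were past the threshold. Where the main fit or the alternative called a result, none had the opposite direction in the other fit. Changes of direction between fits that both left a result uncalled were not counted. The filters on cRPKM and limma left some results untested. The limits of 2-fold and of an adjusted p under 0.01 were applied to the counts only. Many of the 166 calls were lost without untreated replicate 1 or untreated replicate 2. Fewer were lost without either 0.5 h library, and fewest without a 3 h library. With only the libraries compared 51 were lost; the replicate block lost none and added 81, DESeq2 lost none and added 63, DESeq2 with the block lost none and added 100, and limma with 1 added to cRPKM lost 14 and added 19. Beyond the values printed beside results, the block changed no other call except by adding some.

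At 0.5 h the 6 genes called higher became 13 without a filter, 35 in DESeq2, 48 in DESeq2 with the block, 11, 10 and 10 in limma with 1, 0.1 and 5 added to cRPKM, 13 with the block, 10 with the length and GC correction, 13 with both and 2 at an adjusted p under 0.01. The 0 called lower became 2 in DESeq2, with or without the block, 2 in limma with 1 or 0.1 added and 1 with 5 added. With 1 library left out the counts ran from 0 to 4 higher and stayed at 0 lower.

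At 3 h the 1384 higher and 1088 lower became 2276 and 1857 in DESeq2, 3148 and 2918 in DESeq2 with the block, 2963 and 2955 with the block, 2871 and 3263 with block and correction, 743 and 336 with only the libraries compared, 583 and 256 at 2-fold or more, and 236 and 78 at an adjusted p under 0.01. With 1 library left out they ran from 34 to 1935 higher and from 4 to 1821 lower. Between the times, 1015 and 774 became 1942 and 1606 in DESeq2, 2776 and 2480 in DESeq2 with the block, 2477 and 2484 with the block, 2480 and 2661 with block and correction, 349 and 111 with only the libraries compared, 426 and 170 at 2-fold or more, and 46 and 12 at an adjusted p under 0.01; limma called 671, 661 and 653 higher with 1, 0.1 and 5 added. With 1 library left out these ran from 0 to 1552 higher and from 0 to 1399 lower. The 6 genes higher at both times became 13 with the block and 2 at an adjusted p under 0.01. Over all genes the covariance of the changes at both times, 0.0462, stood against 0.0437 in simulations of independent libraries and 0.0131 in simulations that kept each gene's replicate effect. Where fewer libraries or a stricter limit entered, fewer degrees of freedom or genes follow by construction; otherwise the cause was not tested.

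Camera called 5 lists higher and 7 lower at 0.5 h, 10 and 6 at 3 h, and 10 and 5 between the times; with an estimated correlation these were 1 and 0, 0 and 0, and 0 and 0. DESeq2 size factors, the filters on cRPKM, and the length and GC correction at 3 h and between the times left the gene counts within 1.5 times.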

Other observations

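The tests of library depth, of immature neurons and of fewer neurons, and the zinc finger family, were chosen only after the result was seen. Genes of the zinc finger transcription factor family (symbols beginning with Zfp or Zbtb and a digit, Zkscan, Zscan, Zik1, Rslcan or Znf) were called lower at 3 h more often than other genes. Of 422 tested, 107 were lower and 23 higher, so that 25.4% fell against 6.34% of other genes, with a median log2 change of −0.33 (edgeR calls; camera p = 1e-07; p = 0.16 with an estimated correlation). With the block 181 were lower and 38 higher (42.9% against 17.9%), and with the length and GC correction 111 and 24. Over all genes far fewer were called lower without untreated replicate 1 or 2. Those fits have fewer degrees of freedom and a lone untreated library. Calls lost there do not show whether the falls depend on both. At 0.5 h none was called in edgeR, with or without the block (median −0.01), and between 0.5 h and 3 h 84 were lower and 20 higher (19.9% against 4.46% of other genes). Reads shared between relatives of this family may blur single members, which the deposited counts do not resolve; the length and GC correction left 24 higher and 111 lower, and other artefacts were not tested.

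Egr1, a classical immediate early gene singled out after its values were seen, stood at 36.0 and 17.2 cRPKM in the untreated libraries, 160 and 125 at 0.5 h and 48.8 and 39.7 at 3 h (log2 change 2.39 ± 0.39 at 0.5 h, adjusted p = 0.55; 0.79 ± 0.37 at 3 h, 0.19, and 0.025 with the block). Homer1, a scaffold gene of the effector list singled out in the same way, stood at 12.5 ± 0.35, 12.6 ± 0.46 and 24.4 ± 4.8 (1.03 ± 0.17 at 3 h, adjusted p = 0.019).

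Of 15895 tested genes, 2813 were near silence in untreated neurons (a mean under 0.5 cRPKM), and 2728 of these had a position in the reference. Among the 2728, 196 were higher and 31 lower at 3 h, beside 1384 and 1088 over all tested genes. The choice by a low untreated level itself favours rises over falls. Far fewer genes were called higher without either untreated library, in fits with fewer degrees of freedom. Those fits do not show whether the rises depend on both libraries. The 196 were 14.2% of all genes called higher and reached a median of 0.42 cRPKM. The median of their lower 3 h count was 70. The rule set beforehand read a median of this size as going against few counts. It was not used so, because a call at 3 h itself asks for counts there. For the set as a whole, few counts therefore cannot be told apart from a rise by this value. Overlap with exons of another expressed gene touched 22 of the 196 (11.2%) against 7.35% of the rest (odds ratio 1.59, 95% interval 0.95 to 2.57). As the cause for the whole set it is argued against, since most members overlapped no such exon. For the 22 that did, it stays open. Transcription running past the 3′ end of an expressed neighbour is a candidate explanation for part: a facing 3′ end of a gene of at least 5 cRPKM lay within 20 kb of 55.1% of them (108 of 196) against 31.9% of other near-silent genes (807 of 2532; odds ratio 2.62, 1.94 to 3.56, Fisher's exact test p = 1.66e-10), while facing 5′ ends gave 0.975 (0.676 to 1.38). For 33 members (16.8%) no such 3′ end of a gene of at least 1 cRPKM lay within 100 kb, so a neighbour of that kind does not account for them. Neighbours were chosen in each search by their untreated level, and overlapping genes were left out. Transcription from a gene that rose with KCl, overlapped or lay farther away was not tested. Induction by KCl of the genes themselves stays open. Fosl1, Ptgs2 and Gprc5a lack such a neighbour within 20 kb, while Nhlrc4, Aoc3 and Klhl30 have one.

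Many differences between replicates 1 and 2 recurred in every group, with 1103 genes higher and 800 lower in replicate 2 over all libraries. Library depth is argued against, since among 4266 genes of at least 20 cRPKM the replicate differences still correlated between groups with r of at least 0.50. Choroid plexus tissue in the replicate 2 cultures is a candidate explanation for part: of 17 choroid markers besides Ttr, 16 were higher in replicate 2 in all 3 groups, with a median log2 difference of 1.80 at the least (1.80, 2.10 and 2.65), and Ttr itself stood at 136 to 229 cRPKM against 0.04 to 0.13. Whether replicate 1 held more immature neurons cannot be told apart from other differences: 10 immature neuron markers were higher there by a median of at least 0.64 (0.68, 0.64 and 1.01), but 104 synapse genes went lower by 0.15 and 0.06 in untreated and 0.5 h libraries and higher by 0.29 at 3 h. The embryos or days behind the numbers are not given in the sources used here.

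At 3 h the synapse and channel lists had lower values and the ribosomal list higher ones, as called by camera but not with an estimated correlation (adjusted p = 0.76 and 0.6). After removal of the trend with transcript length and GC content the medians kept their direction and most of their size. They were −0.44 before and after for excitatory synapse, −0.39 and −0.33 for calcium and sodium channels, and 0.41 and 0.31 for ribosomal proteins. This argues against that trend as the whole cause of the shifted medians. Camera at the preset correlation still called all 6 lists (largest adjusted p 0.015). It was not repeated there with an estimated correlation, so that call does not decide the question. Fewer neurons among the cultured cells cannot be told apart from a change within them: the median of 194 synapse and channel genes lay below that of 11 pan-neuronal markers by a log2 difference of −0.20 (−0.39 against −0.19), with a bootstrap interval that reached 0 (−0.31 to 0), while astrocyte (0.37), oligodendrocyte (0.28), fibroblast (0.15) and progenitor (0.57) marker medians were above 0 and that of interneuron markers below it (−0.44). The 3 h libraries also differed from each other. There the synapse and channel lists were lower in replicate 2 by medians of −0.24 to −0.38, and the ribosomal list was higher by 0.21. In untreated neurons those lists were 0.11 to 0.21 higher in replicate 2, and the ribosomal median was −0.08. How far the pattern rests on 3 h replicate 2 was not tested, so a difference of that library or culture stays open. A response of the neurons to 3 h of KCl, which the design names, stays open as well.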
